A study of Mus musculus with 6 samples.

How the data were processed

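The data are 6 RNA-seq libraries of mouse retina, 3 of rod-specific Dicer1 conditional knockouts (cKO replicates 2, 3 and 4) and 3 of control littermates (replicates 1, 2 and 3), grouped by the source name in the labels. Per the labels' protocols, 2 retinas were homogenized at a time, total RNA of 4 mice at 4 weeks of age was pooled for each library, and 400 to 450 ng of poly(A) RNA was reverse transcribed with random primers. The protocol describes an ordinary second strand synthesis, so reads carry no strand, and reads of overlapping or antisense genes cannot be told apart.

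The authors deposited 1 table with an RPKM value per gene and library, printed to 5 decimals. Per the submitters' processing notes, GSNAP, HTSeq and the mm9 build were used, with no versions. The annotation, the length model behind the RPKM, which reads the depth counts, and how reads with several matches were treated are not given in the sources used here. RPKM divides by length and depth, so a change in a few abundant genes shifts the other values, and a trend with gene length or fragment length stays in them. Every sample column was used.

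Read numbers were worked back from the RPKM values. Within a gene the values are whole multiples of a step taken as 1 read, which gives the libraries' relative depth, and the lengths of 342 genes with a single annotated transcript in GENCODE M21 set the scale. In a first pass 1.04% of the counts of cKO replicate 4 above 0 were odd, against at least 52.0% in each other library, so its denominator was halved and the reads were worked out again, which left 51.8% odd. The values cannot show whether its reads were instead counted 2 times. Whole reads were found for 100% of the 19140 genes above 0, and the deposited values were returned within 1e-05 in all of them. A length was accepted only where every value fell on whole reads within rounding, so this return follows from the rule and is no separate check. The denominators were 24518872, 35846244 and 15128203 reads for cKO replicates 2, 3 and 4 and 34432874, 38982103 and 40523119 for control replicates 1, 2 and 3, and between 77.2% and 81.5% of these fell in the genes of the table. On simulated data for 6000 genes the step returned 6 of 6 denominators exactly. It gave exact reads for 99.1% of the 3939 genes with a mean of at least 1 RPKM. In that simulation 2 denominators were also halved, so a halving can occur without reads being counted 2 times. Between 4520 and 5924 genes were at 0 in a library. The recovered lengths stand for the authors' gene models and equal an annotated transcript for 1577 of the 11425 tested symbols found in GENCODE M21.

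Since RPKM values are not counts, the main test was limma (R 4.3.3, limma 3.58.1) on log2(RPKM + 0.5), with a variance trend and no block or covariate, for the 12599 genes with a mean of at least 1 RPKM over the 6 libraries. Values were used as deposited. Two-sided p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Single genes were also compared by an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3 libraries. Fold changes are on the log2(RPKM + 0.5) scale. With 3 pooled libraries per group, the spread is that between pools of mice. Reads were simulated for these 12599 genes, and the changed genes were drawn from those with a mean of at least 50 reads. The test called 89 of 100 genes changed by 1 and 50 of 100 changed by 0.6 on the log2 scale. It called 10 unchanged genes, and its rate for changed genes with fewer reads was not measured. With no change simulated it called 0 genes and 0 lists. The simulated genes varied independently, unlike real ones.

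Gene lists for retinal cell types, other tissue a dissected retina can hold, photoreceptor function, microRNA biology, stress and metabolism were fixed before the data were examined, and the 38 lists with at least 5 genes measured were tested with camera at a preset correlation of 0.01, over all lists. The red blood cell list (2 genes measured) and the skeletal muscle list (4 genes measured, Acta1, Ckm, Mylpf and Pvalb) were too small to test. Camera with an estimated correlation and the directional test of fry were run beside it. The mixed test of fry was not among the planned tests. For 17 microRNA families, tested genes with a 7-base seed site in their longest annotated 3′ UTR (GENCODE M21) were set against as many genes with no site for that family, matched on UTR length, UTR GC and expression. The matched genes could hold sites for other families. A 3′ UTR was found for 11048 tested genes, or 87.7%. Coordinates are from GENCODE M21 on GRCm38, not the build the authors used, and serve only to place genes.

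The genes named follow a rule fixed before the data were examined. It names Dicer1 first, then up to 10 genes in each direction with the largest change among those past the threshold whose 3 cKO values all lie outside the range of the 3 control values. Where fewer than 5 passed in a direction, it takes the 10 with the smallest p, and unnamed transcripts are named only if among the 3 largest of their direction. For each list described it takes up to 3 members past the threshold and the most abundant one, and where none passed, the most abundant and the one with the largest moderated statistic. Under this rule 1 unnamed transcript in the lower direction was counted but not named, and a few genes that the rule takes are not described here. Ier2, Junb, Atf3, Lhx1, Prdm1, Edn2, Cp, Gapdh, Gfap, Ddx3y, Oaz3, Mir3062 and Mir466i were named after their values were seen.

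The alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter on low values, a mean of at least 5 RPKM, median-of-ratios and quantile normalization, scaling to the total without the 50 most abundant genes, limma without trend, with robust variances or with array weights, a replicate block, and each library left out in turn. For lists they were the estimated correlation and fry, and for microRNA sites 8-base sites only or all genes without a site. Chosen after seeing the data were corrections for gene length and for gene length with GC (splines with 5 df), the first residual component as a covariate, limma voom on the recovered reads with 2 scalings, the libraries of the block without it, and a fit without the outer libraries. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for recovery of reads, and figures were drawn with matplotlib 3.10.9.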

Results

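The retinal transcriptome was measured by RNA sequencing in mice that lack Dicer1 in rod photoreceptors and in their control littermates. Dicer1 encodes the ribonuclease that cuts microRNA precursors into mature microRNAs. Both groups carried floxed Dicer1 alleles, and only the conditional knockout (cKO) mice carried the iCre75 transgene, which expresses Cre recombinase in rods. Each group had 3 libraries, and each library was made from poly(A) RNA pooled from 4 mice at 4 weeks of age, with retinas collected between 8 and 10 in the morning. The design text calls the libraries biological replicates. The deposited table gives RPKM (reads per kilobase of gene model, scaled to depth) for 22731 gene symbols, of which 12599 had a mean of at least 1 RPKM and were tested. Whole read numbers worked back from the RPKM steps gave 19187838, 29007472 and 12336599 reads in genes for cKO replicates 2, 3 and 4, and 27204998, 30113335 and 32935029 for control replicates 1, 2 and 3. A gene of the median length, 2857 bp, at 1 RPKM then rests on between 43.2 and 116 reads per library. Pairs of libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom between 9.65 and 30.3, so no 2 of them are copies of 1 library.

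Dicer1 itself, on chromosome 12 (104687742 to 104751952 in GRCm38), was measured at 8.52 ± 0.222 RPKM in control retinas and 7.66 ± 0.525 RPKM in cKO retinas (SD, n = 3 each), or 89.9% of the control mean. All 3 cKO values, 8.02, 7.06 and 7.90 RPKM, lay below the 3 control values, 8.48, 8.77 and 8.33 RPKM. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow, and the limma log2 fold change of −0.15 ± 0.08 (SE) did not pass adjustment over all genes (adjusted p = 0.931). Without cKO replicate 3 it was −0.092, and without each other library between −0.18 and −0.13. A gene-level value also counts reads from exons outside the floxed part and from retinal cells that keep Dicer1, so it is a weak check of the genotype. Of the 16 measured genes of the microRNA pathway list, which holds the nuclear processing enzyme Drosha and the Argonaute genes, 13 had a lower and 3 a higher mean log2 value in cKO, and the list did not pass (mean log2 fold change −0.044, camera adjusted p = 0.511). Drosha, its most abundant member, was at 17.4 ± 0.947 RPKM in controls and 16.9 ± 0.676 RPKM in cKO. Eif2c3, an Argonaute gene with the largest moderated statistic of the list, was at 2.34 ± 0.339 and 1.79 ± 0.327 RPKM (limma adjusted p = 0.874).

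**Figure D1:**
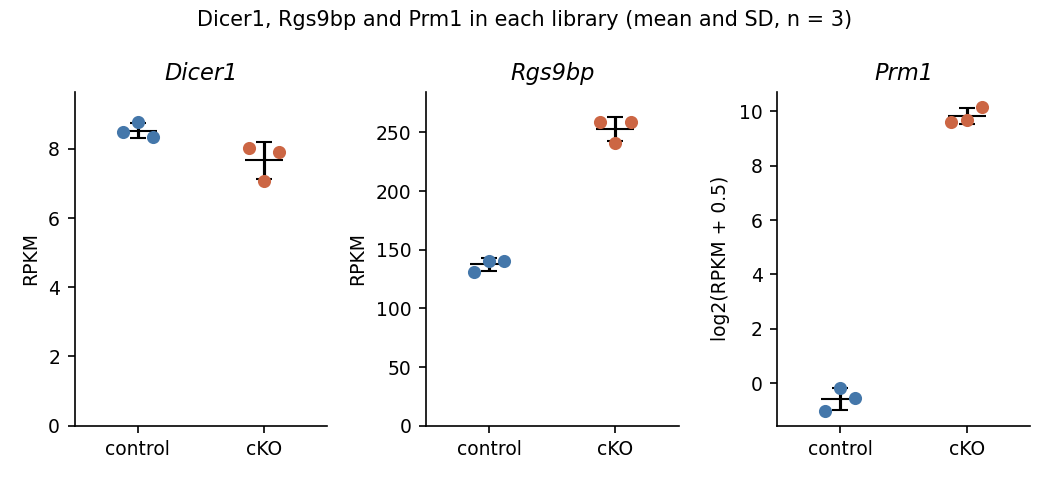
Deposited RPKM of Dicer1 and Rgs9bp, and log2(RPKM + 0.5) of Prm1, in the 3 control and 3 cKO libraries; points are libraries, and black bars show the mean and SD. Dicer1 lies between 8.33 and 8.77 RPKM in controls and between 7.06 and 8.02 RPKM in cKO, Rgs9bp averages 138 RPKM in controls and 253 RPKM in cKO, and Prm1 is near 0 in controls only.

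Prm1, which encodes protamine 1, the protein that packs DNA in sperm, was the 1 gene that passed an adjusted p of 0.05. It was at 787, 818 and 1137 RPKM in the cKO libraries (7716, 11727 and 6878 reads) and at 0, 0.385 and 0.185 RPKM in the controls (0, 6 and 3 reads). The log2 fold change was 10.39 ± 0.22 (SE, limma adjusted p = 7.47e-07) on the log2(RPKM + 0.5) scale, which understates the change of a gene near 0. Prm1 lies on chromosome 16 (10796326 to 10805839 in GRCm38), beside Prm2, Prm3 and Tnp2, none of which was above 0.187 RPKM in any library. Prm1 passed in every alternative run, including each fit that left out 1 library. All cKO libraries and no control library came from mice with the Cre transgene. Reads from the transgene counted as Prm1 therefore cannot be told apart here from a response to the loss of Dicer1, as set out further below.

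No gene passed in the lower direction in the test as set out. With no filter on low values, limma called 2, Mir3062 and Mir466i, each resting on 1 read per control library and 0 in cKO. Of the alternatives chosen after seeing the data, limma voom on recovered reads called Dusp1, and voom with median-of-ratios scaling called 0 lower. The length and GC correction called Dusp1 too, and the length correction alone called 0 lower. The fit without the outer libraries, cKO replicate 4 and control replicate 3, called Egr1. The first residual component as a covariate called 17 lower, with p-values that are too small, and limma with array weights, a fit that did not converge, called 3103. The planned replicate block, on samples that share only a number and with 1 residual degree of freedom, called 106 lower. The same libraries without the block gave 0 lower. At an unadjusted limma p under 0.05 there were 334 genes higher and 385 lower in cKO, where chance alone would give about 630 in all. The 3 cKO values lay above all 3 control values for 745 genes and below them for 728, together 11.7% of those tested, where chance gives 10%. The other genes named here are those with the smallest p in each direction, and none of them passed the adjusted threshold.

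Rgs9bp, whose product anchors the RGS9 complex that shuts off rod and cone transducin at the disc membrane, came closest. It was at 138 ± 5.48 RPKM in control and 253 ± 10.3 RPKM in cKO retinas (SD, n = 3), a log2 fold change of 0.88 ± 0.09 (SE) with a limma adjusted p of 0.0692. This gene lies on chromosome 7 (35578993 to 35585582 in GRCm38). Its call turned with the setting: it passed in 9 of 22 alternatives other than array weights and the replicate block, with log2 fold changes between 0.82 and 0.91 over all of them. The unnamed transcript 2610528A11Rik was at 1.85 ± 0.241 RPKM in controls and 4.00 ± 0.428 RPKM in cKO (limma adjusted p = 0.0957). It passed in 5 of 21 alternatives other than array weights and the replicate block. Slc38a3, a glutamine transporter, was at 260.04 ± 11.5 and 369 ± 16.4 RPKM, and Pigs, a subunit of the GPI transamidase, at 39.9 ± 1.38 and 55.2 ± 1.08 RPKM. Nrtn, which encodes the growth factor neurturin, was at 26.7 ± 0.366 and 37.5 ± 1.56 RPKM, and the RNA-binding protein gene Lsm14b at 20.4 ± 1.44 and 30.1 ± 1.02 RPKM. Selenbp1, Emid2, and the GATA cofactor gene Zfpm1 had log2 fold changes of 0.54, 0.60 and 0.56. The limma adjusted p of these 7 genes lay between 0.173 and 0.424, and in each of them the 3 cKO values lay above the 3 control values.

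In the lower direction, Hdc, the enzyme that makes histamine, was at 3.57 ± 0.215 RPKM in controls and 1.92 ± 0.104 RPKM in cKO (log2 fold change −0.75 ± 0.08 SE, limma adjusted p = 0.0957). Dusp1, a phosphatase that acts on MAP kinases, was at 22.2 ± 1.71 and 13.4 ± 0.299 RPKM (−0.70 ± 0.08 SE, limma adjusted p = 0.0957). Fos and Egr1, transcription factors of the immediate early response, were at 24.9 ± 1.32 and 15.02 ± 1.72 RPKM and at 22.4 ± 4.66 and 11.9 ± 0.429 RPKM. Fam164c, Glb1l3, the kinase signalling inhibitor gene Spry4 and the transcription factor gene Mef2c had log2 fold changes of −0.58, −0.79, −0.71 and −0.47. Hist2h4, a histone H4 gene, had one of −0.65, but it has near-identical copies whose reads the counting could split, so its value is uncertain. The limma adjusted p of these 7 genes lay between 0.158 and 0.422.

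As a group, immediate early genes, which neurons and glia switch on within minutes of stimulation, were lower in cKO retinas. Of the 16 measured, 15 had a lower mean log2 value in cKO, with a mean log2 fold change of −0.30, a median of −0.24 and a camera adjusted p of 3.99e-10 over the 38 lists tested. The p was 0.0152 with an estimated correlation (adjusted p = 0.578) and 0.00421 by fry (adjusted p = 0.160), so the call did not hold over all lists by either. None of the 16 passed over all genes tested, and Dusp1, Fos, Egr1, Ier2, Junb and Atf3 passed when adjusted over the list alone, all 6 lower. Ier2 was at 23.1 RPKM in controls and 17.4 RPKM in cKO, Junb at 13.8 and 10.4 RPKM and Atf3 at 3.19 and 2.27 RPKM. Jund, the most abundant member, was at 60.6 ± 2.66 RPKM in controls and 62.1 ± 1.84 RPKM in cKO. At the preset correlation the list passed without each library in turn, with mean log2 fold changes between −0.33 and −0.26. The fits that left out 1 library share most of their libraries, so these passes are not independent. That test also passed this list in some splits of the libraries that mix the groups (lowest camera adjusted p 2.89e-05). Such splits stay uneven in genotype, so a real difference would enter them in part. They cannot decide whether the test passes too readily. Causes other than the loss of Dicer1 stay open, as set out further below.

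**Figure D2:**
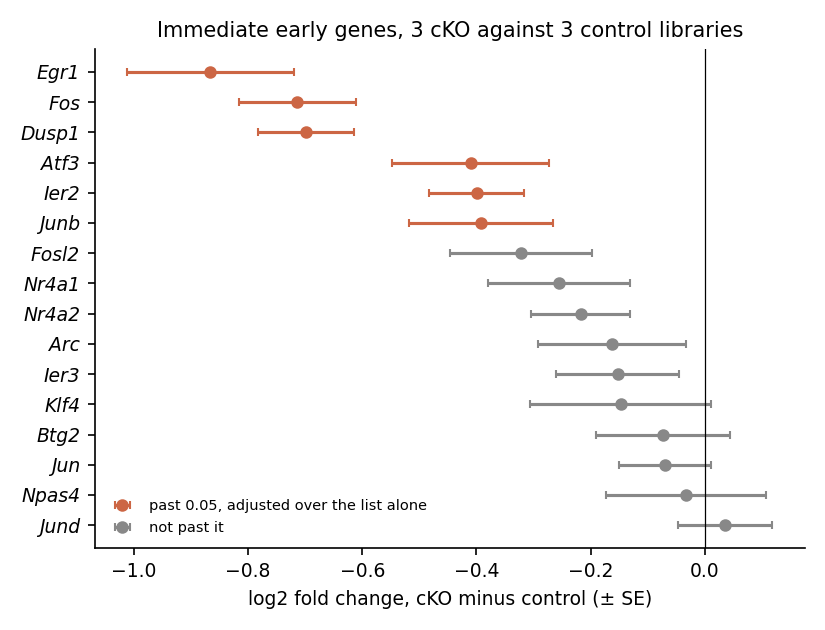
Log2 fold change (cKO minus control, on log2(RPKM + 0.5)) and its limma SE for the 16 measured immediate early genes, from 3 libraries per group; orange points passed 0.05 when adjusted over the list alone. The points run from −0.87 for Egr1 to 0.036 for Jund, and 15 of 16 lie below 0.

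Glycolysis genes were higher as a list: 18 of 20 measured had a higher mean log2 value in cKO, with a mean log2 fold change of 0.10 and a camera adjusted p of 0.0134. With an estimated correlation the p was 0.126 (adjusted p = 0.798), and none of its genes passed over all genes or when adjusted over the list alone. Pdk1, the kinase that restrains pyruvate dehydrogenase, was at 8.62 ± 0.239 RPKM in controls and 10.4 ± 0.641 RPKM in cKO, and Aldoa, the most abundant member, at 1309 ± 203 and 1341 ± 144 RPKM. Without control replicate 2 the mean was 0.059 and the adjusted p 0.0604. Cytosolic ribosomal protein genes were lower as a list, 54 of 69, with a mean log2 fold change of −0.088 and a camera adjusted p of 0.0317. With an estimated correlation the p was 0.581 (adjusted p = 0.934), and no member passed adjusted over the list alone. Rpl8, the most abundant, was at 412 ± 75.6 RPKM in controls and 369 ± 50.9 RPKM in cKO, and Rpl12 at 3.10 ± 0.192 and 2.41 ± 0.534 RPKM. The call rested on single libraries: the mean was 0.017 without cKO replicate 2 (adjusted p = 0.805), −0.055 without control replicate 1 (0.181) and −0.0070 without control replicate 3 (0.669). Both lists hold genes with many near-identical pseudogenes, such as Gapdh, listed at 8.83 RPKM in controls, and reads shared with such copies make their levels uncertain.

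No list of rod or photoreceptor genes passed as higher or lower as a whole. The 21 measured genes of rod phototransduction had a mean log2 fold change of −0.022 (camera adjusted p = 0.511), and 1 of them, Rgs9bp, passed when adjusted over the list alone. The mean of this list was 0.0025 without cKO replicate 2 and 0.025 without control replicate 3. The outer segment and cilium list (23 genes) had a mean of −0.019 (adjusted p = 0.774), with Unc119 at 1884 ± 205 and 1933 ± 115 RPKM and the axonemal gene Rp1 at 92.3 ± 2.46 and 79.8 ± 7.42 RPKM. Among 15 rod transcription factors (adjusted p = 0.951), Nrl, which specifies rod fate, was at 862 ± 118 and 829 ± 72.9 RPKM, and Mef2c and Prdm1 passed adjusted over the list alone, both lower. The visual cycle list (12 genes, adjusted p = 0.951) held Rbp3 at 894 ± 43.5 and 978 ± 91.0 RPKM and the retinol dehydrogenase gene Rdh12 at 202 ± 26.5 and 153 ± 17.7 RPKM. The photoreceptor synapse list (19 genes, adjusted p = 0.951) held the glutamate transporter gene Slc17a7 at 730.1 ± 97.7 and 849 ± 143 RPKM and Pclo at 5.23 ± 0.479 and 4.52 ± 0.327 RPKM. For the last 3 lists the mean was below 0 (−0.0019, −0.012 and −0.0013 in that order) and the median and the test direction above 0.

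No marker list of another retinal cell type passed. Cone markers (18 genes) had a mean log2 fold change of 0.051 (camera adjusted p = 0.511), with Gnb3 at 247 ± 31.9 RPKM in controls and 277 ± 30.8 RPKM in cKO and Otop3 at 6.12 ± 0.485 and 7.71 ± 1.04 RPKM. Horizontal cell markers (9 genes) were nearest, with a mean of 0.10 and an adjusted p of 0.0513. In that list, Slc4a3 at 32.3 ± 0.905 and 39.1 ± 0.958 RPKM and Lhx1 at 2.61 and 3.26 RPKM passed adjusted over the list alone, and Sept4, the most abundant, was at 118 ± 17.8 and 123 ± 18.5 RPKM. The list passed in 11 of 26 alternatives, among them the fits without cKO replicate 4 (adjusted p = 0.0426) and without control replicate 1 (0.0265), and was furthest from passing without cKO replicate 3 (mean 0.082, 0.129) among the fits that left out 1 library. Bipolar markers (20 genes) had a mean of 0.070 (adjusted p = 0.0997) and passed in 2 of 26 alternatives, those corrected for gene length. Amacrine markers (16 genes, mean 0.020, adjusted p = 0.542) held Calb2 at 267 ± 38.6 and 255 ± 22.4 RPKM and Slc18a3 at 11.5 ± 0.780 and 13.0 ± 0.936 RPKM. Ganglion cell markers (20 genes, mean 0.0071, adjusted p = 0.870) held Nefl at 224 ± 20.4 and 213 ± 11.3 RPKM and Eomes at 1.94 ± 0.0990 and 2.42 ± 0.197 RPKM. Müller glia markers (22 genes) had a mean of −0.034 (adjusted p = 0.548), with Apoe at 1097 ± 101 and 1004 ± 49.9 RPKM and the water channel gene Aqp4 at 15.4 ± 0.447 and 13.6 ± 0.535 RPKM. Astrocyte (6 genes), vascular (17) and pigment epithelium markers (15) had means of −0.034, −0.011 and 0.066 (adjusted p = 0.568, 0.870 and 0.140). The pigment epithelium list passed in 4 of 26 alternatives, without cKO replicate 4 among them (mean 0.15, adjusted p = 0.0124), and its mean was −0.022 without cKO replicate 2 and 0.017 without control replicate 3.

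Genes of glial or photoreceptor injury did not rise as a list, though its members went both ways: 7 had a higher and 11 a lower mean log2 value in cKO. The 18 measured genes of that list had a mean log2 fold change of −0.092 (camera adjusted p = 0.385), and 3 of them passed adjusted over the list alone, all lower: Edn2, an endothelin gene, at 3.87 RPKM in controls and 1.85 RPKM in cKO, Cebpd at 3.68 ± 0.287 and 2.50 ± 0.414 RPKM, and the copper-binding protein gene Cp at 16.1 and 12.4 RPKM. Gpr37, the most abundant, was at 49.4 ± 2.01 and 51.1 ± 1.84 RPKM, and the glial filament gene Gfap at 9.72 ± 1.29 and 9.40 ± 1.13 RPKM. The list passed as lower without cKO replicate 2 (mean −0.14, adjusted p = 0.0186), and its mean without each other library lay between −0.12 and −0.068. Microglia and macrophage markers (17 genes) had a mean of −0.079 (adjusted p = 0.140), with Lgals3 at 2.08 ± 0.350 and 1.66 ± 0.184 RPKM, and passed without control replicate 2 (mean −0.13, 0.0223), against a mean of −0.047 without control replicate 1. Apoptosis and p53 genes (23, mean −0.041, adjusted p = 0.511) held Bax at 35.3 ± 3.37 and 36.7 ± 3.72 RPKM and Bcl2 at 1.77 ± 0.102 and 1.29 ± 0.144 RPKM. Necroptosis and inflammasome genes (5), unfolded protein response genes (22), oxidative stress genes (17) and interferon response genes (14) had means of −0.056, −0.031, −0.055 and −0.027 (adjusted p = 0.548, 0.511, 0.548 and 0.864). Heat shock genes (12) had a mean of −0.12 (adjusted p = 0.0997) and passed in 7 of 26 alternatives, without control replicate 2 among them (mean −0.25, 0.00551). That mean was −0.031 without control replicate 1 (0.552) and −0.077 without control replicate 3 (0.214), and the adjusted p over all alternatives ran from 0.00551 to 0.941.

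Among the remaining lists, circadian clock genes (19, mean log2 fold change 0.019, camera adjusted p = 0.928) held the dopamine receptor gene Drd4, at 284 ± 26.7 RPKM in controls and 392 ± 25.2 RPKM in cKO. Autophagy (17 genes), oxidative phosphorylation (83), cholesterol synthesis (16) and cell cycle genes (9) had means of 0.017, −0.029, −0.0076 and −0.012 (adjusted p = 0.568, 0.610, 0.992 and 0.952), and the median of the cell cycle list was above 0. Oxidative phosphorylation passed in 5 of 26 alternatives, among them as lower without cKO replicate 4 (adjusted p = 7.14e-04) and without control replicate 2 (0.00343), and as higher without cKO replicate 2 (mean 0.11, 0.0143). Replication-dependent histones (16) had a mean of −0.13 and a median of −0.046 (adjusted p = 0.0521) and passed in 7 of 26 alternatives, without cKO replicate 4 among them (mean −0.27, 8.69e-05). That mean was −0.060 without cKO replicate 2 (0.161) and −0.055 without cKO replicate 3 (0.418), and the adjusted p over all alternatives ran from 8.69e-05 to 0.958. Lens genes differed between single libraries: Cryaa, the main crystallin, ranged from 79.9 RPKM in cKO replicate 4 to 1488 RPKM in control replicate 1, and Crygb was at 42.8 ± 19.6 RPKM in controls and 28.2 ± 16.8 RPKM in cKO. All 21 lens genes had a lower mean in cKO (mean −0.40, adjusted p = 0.104), and the list passed in 6 of 26 alternatives, as higher in 2 of them and as lower in 4, among these the fits without cKO replicate 2 (0.0143), cKO replicate 3 (1.20e-07) or control replicate 2 (3.11e-05). Its mean turned to 0.35 without cKO replicate 4 and to 0.15 without control replicate 1. Ciliary body, iris and cornea markers (12) had a mean of −0.044 (adjusted p = 0.474), with a call without cKO replicate 2 (mean −0.16, 0.0343), and its mean was 0.10 without cKO replicate 4 and 0.078 without control replicate 2. Sex-linked transcripts (5, adjusted p = 0.0513) showed unequal pools of male and female mice: Xist was at 0.0065 RPKM in control replicate 1 and 27.1 RPKM in control replicate 3, and the Y-linked gene Ddx3y at 5.97 and 0 RPKM in the same libraries. Kdm5d, another Y-linked gene, was at 1.16 ± 1.495 RPKM in controls and 2.17 ± 0.561 RPKM in cKO, and the list passed in 10 of 25 alternatives, among them those without control replicate 1 (6.64e-05) or control replicate 2 (0.0223). Its mean of 1.02 was 0.53 without control replicate 3 (0.322). The mixed test of fry, not among the planned tests, asks whether the genes of a list change in either direction and compares the list with no other. It passed for 6 of the 38 lists, namely rod phototransduction (adjusted p = 3.96e-04), rod transcription factors (0.00213), immediate early genes (0.00269), circadian clock genes (0.0393), and injury genes and horizontal cell markers (0.0440 each).

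**Figure D3:**
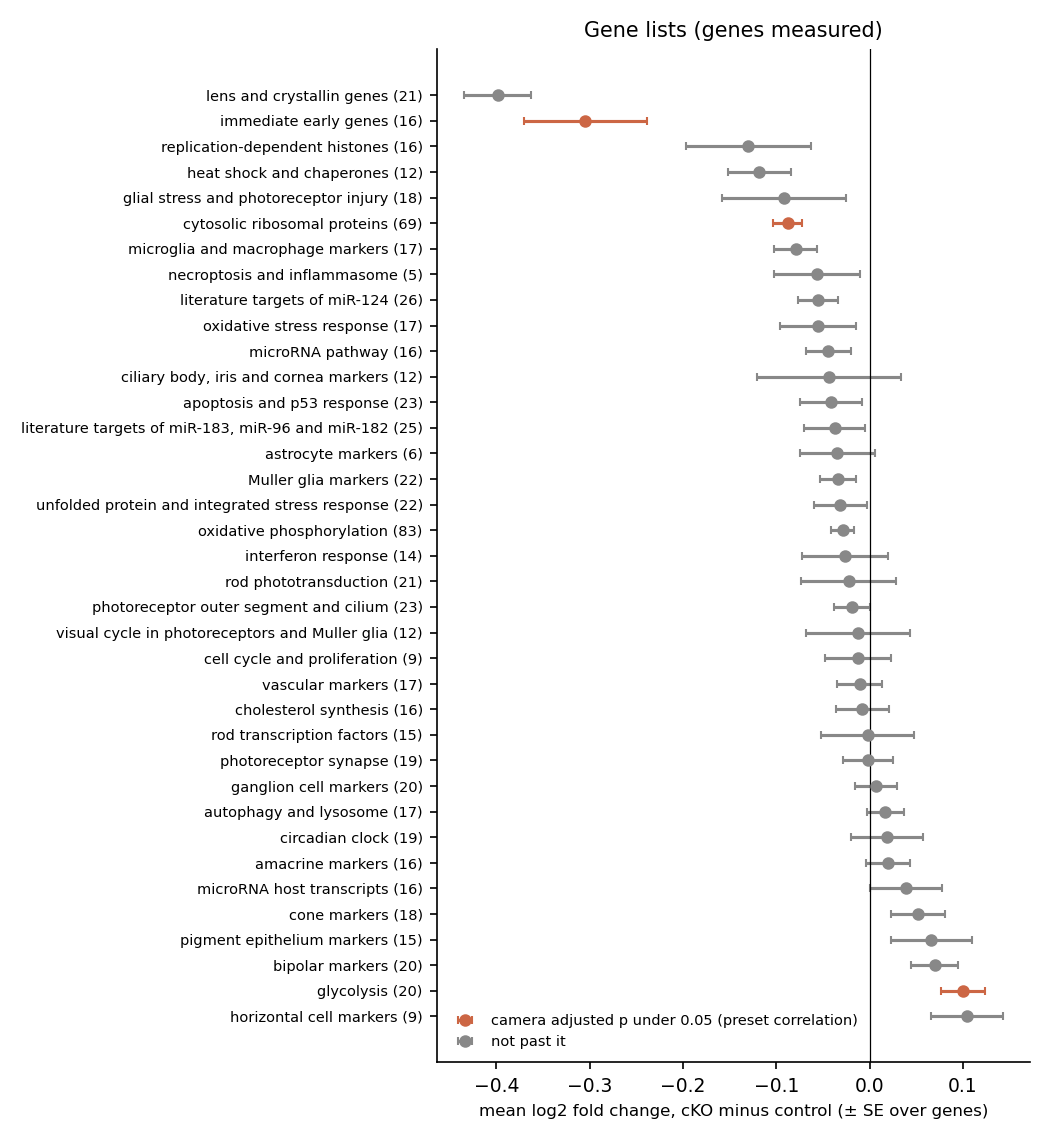
Mean log2 fold change (cKO minus control) of 37 of the 38 gene lists tested, with the SE over the genes of each list and the number of genes measured in parentheses; the sex-linked list, with a mean of 1.02, lies off this scale and is left out. Orange marks the 3 lists past a camera adjusted p of 0.05 with the preset correlation: immediate early genes and ribosomal proteins below 0 and glycolysis above it.

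The design asks whether messages that microRNAs would hold down rise when rods lose Dicer1. Genes with a site for the photoreceptor microRNAs miR-183, miR-96 and miR-182 in their 3′ UTR differed from matched genes without one by −0.0100, −0.0016 and −0.0041 in mean log2 fold change, over 1905, 2267 and 2339 genes. For miR-124, abundant in neurons, the difference was 4.71e-04 over 2662 genes. Over the 12 retinal and 5 comparison families, differences ran from −0.012 for miR-181 to 0.0041 for miR-1, a comparison family, and 0 families passed in either direction (camera adjusted p = 0.990 for each). With an estimated correlation the adjusted p was at least 0.981, and 0 families were at an unadjusted p under 0.05 by either. The same test found a simulated rise of 0.1 in genes with miR-124 sites (adjusted p = 6.21e-19). In that simulation only genes with miR-124 sites rose, all by the same amount, and genes varied independently. In the real test the matched genes could hold sites for other families. A rise shared by the targets of many families could therefore be partly lost from the differences, and the 0 families called do not exclude it. Literature targets of miR-183, miR-96 and miR-182 (25 genes) had a mean of −0.037 (adjusted p = 0.544), with Slc6a9 at 88.4 ± 3.08 RPKM in controls and 96.2 ± 4.61 RPKM in cKO and the adenylyl cyclase gene Adcy6 at 41.3 ± 2.39 and 51.6 ± 1.20 RPKM. Literature targets of miR-124 (26 genes) had a mean of −0.055 (adjusted p = 0.0997), with Neurod1 at 143 ± 7.37 and 138 ± 15.3 RPKM. Rhog, at 6.77 ± 0.284 and 5.26 ± 0.132 RPKM, passed adjusted over that list alone, and the list passed as lower without cKO replicate 2 (adjusted p = 0.0186). MicroRNA host transcripts (16) had a mean of 0.039 (adjusted p = 0.568).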

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

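Of 1353 values of named genes, 984 of gene lists and 108 of microRNA families under the alternatives, 1212, 832 and 89 kept their direction and side of the threshold. Few of these results passed in the main fit, so for most of them this means staying uncalled with the same sign. Array weights (2707 genes higher and 3103 lower) gave cKO replicate 3 a weight of 17.6 and stopped before convergence. Replicate numbers 2 and 3 occur in both groups and the samples share only a number: after the group means, libraries with the same number correlate at 0.465 and −0.052, and the block leaves 4 libraries and 1 residual degree of freedom. The length, GC, component, voom and outer-library settings were chosen after seeing the data, and the component is estimated from the same residuals, so its p-values are too small. The causes of the differences below were not tested. With 43.2 to 116 reads for 1 RPKM at the median length, genes near the filter rest on few reads. Values are log2 fold changes, mean differences or counts of calls.

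With a pseudocount of 0.1: lists higher 3. With a pseudocount of 1: Xist −0.099, photoreceptor synapse 5.9e-04, rod transcription factors 0.0025. With no filter: genes lower 2, astrocyte 0.026, necroptosis and inflammasome 0.0013, miR-96 sites 8.7e-05, miR-124 sites −0.0024. With a mean of at least 5 RPKM: genes higher 2, lists lower 4, photoreceptor synapse 0.0090, rod transcription factors 0.023, miR-96 sites 0.0014, miR-182 sites 0.0026, miR-124 sites −2.9e-04. With median-of-ratios scaling: genes higher 3, photoreceptor synapse 0.0042, rod transcription factors 0.0036. With quantile normalization: lists higher 3, autophagy and lysosome −9.8e-04, cell cycle and proliferation 0.013, ganglion cell −4.8e-04. With total without the 50 most abundant genes: genes higher 3, lists higher 4, amacrine −8.8e-04, autophagy and lysosome −0.0042, circadian clock −0.0021, ganglion cell −0.013. With limma without trend: genes higher 2, lists higher 2. With array weights: genes higher 2707, genes lower 3103, lists higher 2, lists lower 4, Dicer1 −0.25, Jund −0.025, Cryaa 0.032, Nrl 0.016, astrocyte 0.031, cell cycle and proliferation 0.056, cholesterol synthesis 0.13, ciliary body 0.031, circadian clock −0.0029, interferon response 0.033, photoreceptor synapse 0.010, rod transcription factors 0.011, visual cycle 0.017, miR-124 sites −0.0091. With the replicate block: genes higher 86, genes lower 106, lists higher 5, lists lower 4, Aldoa −0.032, Sept4 −0.062, Xist −1.76, Cryaa 1.62, Crygb 0.12, Bax −0.017, Unc119 −0.0069, Nefl 0.0082, amacrine −0.016, autophagy and lysosome −0.010, ciliary body 0.094, cone −0.032, lens and crystallin genes 0.90, miR-96 sites 0.0048, miR-182 sites 0.0026. With the same libraries without the block: lists higher 4, lists lower 4, Aldoa −0.032, Sept4 −0.062, Xist −1.76, Cryaa 1.62, Crygb 0.12, Bax −0.017, Unc119 −0.0069, Nefl 0.0082, amacrine −0.016, autophagy and lysosome −0.010, ciliary body 0.094, cone −0.032, lens and crystallin genes 0.90, miR-96 sites 0.0048, miR-182 sites 0.0026. With an estimated correlation: lists higher 0, lists lower 0. With length correction: genes higher 3, lists higher 2, Pclo 0.015, photoreceptor synapse 0.022, rod transcription factors 4.7e-04. With length and GC correction: genes higher 3, genes lower 1, lists higher 4, Jund −0.070, Aldoa −0.0020, Neurod1 0.0029, Unc119 −0.0053, Pclo 0.031, photoreceptor synapse 0.013. With the first residual component: genes higher 18, genes lower 17. With voom: genes higher 2, genes lower 1, lists higher 3, amacrine −0.0053, autophagy and lysosome −0.0035, circadian clock −7.6e-04, ganglion cell −0.0070. With voom with median-of-ratios: genes higher 2, lists higher 3, cholesterol synthesis 0.0034, ciliary body 0.0048, photoreceptor synapse 0.0018. With the outer libraries left out: genes lower 1, Cryaa 0.87, Crygb 0.0052, astrocyte 0.013, cell cycle and proliferation 0.033, cholesterol synthesis 0.074, interferon response 0.082, lens and crystallin genes 0.40, photoreceptor synapse 8.8e-04, vascular 0.011, visual cycle 0.019, miR-124 sites −0.0036. With 8-base sites only: miR-124 sites −0.012. With all genes without a site: miR-124 sites −0.012. With fry: lists higher 0, lists lower 0.

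With 1 library left out in turn: Aldoa −0.069 to 0.15, Bax −0.022 to 0.12, Calb2 −0.18 to 0.023, Cryaa −1.17 to 0.82, Jund −1.3e-04 to 0.058, Neurod1 −0.14 to 0.0054, Nrl −0.12 to 0.059, Sept4 −0.052 to 0.17, Unc119 −0.012 to 0.13, Xist −1.77 to 1.12, lists higher 1 to 3, lists lower 1 to 6. In the same fits: amacrine −0.029 to 0.073, astrocyte −0.055 to 0.0056, autophagy and lysosome −0.051 to 0.073, cell cycle and proliferation −0.042 to 0.039, cholesterol synthesis −0.059 to 0.052, ciliary body −0.16 to 0.10, circadian clock −0.0056 to 0.032, cone −0.021 to 0.12, cytosolic ribosomal proteins −0.20 to 0.017, ganglion cell −0.032 to 0.047, interferon response −0.12 to 0.076, lens and crystallin genes −0.995 to 0.35. In the same fits: oxidative phosphorylation −0.17 to 0.11, photoreceptor synapse −0.012 to 0.013, pigment epithelium −0.022 to 0.15, rod phototransduction −0.058 to 0.025, rod transcription factors −0.010 to 0.0065, unfolded protein response −0.11 to 0.012, vascular −0.029 to 0.012, visual cycle −0.046 to 0.026, miR-124 sites −0.0036 to 0.0039, miR-182 sites −0.0096 to 7.0e-04, miR-96 sites −0.0066 to 0.0016. Means that kept their sign but moved in size: outer segment and cilium −0.047 to −0.0029, Müller glia −0.067 to −0.014, bipolar 0.026 to 0.105, apoptosis and p53 −0.064 to −0.018. Likewise: necroptosis and inflammasome −0.12 to −0.023, oxidative stress −0.089 to −0.032, literature targets of miR-183, miR-96 and miR-182 −0.069 to −0.017.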

Other observations

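The tests of the transgene and of Müller glia or vascular cells, and the counts of genes called in other splits, were chosen only after the results were seen. With the first residual component as a covariate, chosen after seeing the data, 18 of the 19 named genes other than Dicer1 passed, against 1 in the fit as reported. That covariate is estimated from the same residuals, so its p-values are too small.

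Prm1 at a mean of 914 RPKM in cKO retinas is a sperm protein gene in a tissue that lacks sperm cells. RNA of spermatids in the cKO libraries would bring their other abundant transcripts, but the most abundant of 7 tested, Oaz3, reached 0.231% of Prm1 and was at 2.12 RPKM in cKO and 2.65 RPKM in controls. A switched-on protamine cluster would raise its neighbours, and the highest of Prm2, Prm3 and Tnp2 reached 0.00994% of Prm1. Many transgenes end in the polyadenylation sequence of the protamine 1 gene, so reads from the Cre transgene may be counted as Prm1: the lowest cKO library was 2045-fold above the highest control library. The transgene and the loss of Dicer1 go together in all 6 libraries, so these cannot be told apart here, and a response of Prm1 itself to the loss of Dicer1 stays open as a hypothesis.

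Immediate early genes had a mean log2 fold change of −0.30 in cKO. A gene-length trend between libraries is argued against as the whole cause, since the mean was −0.31 after each library was corrected for length and the list still passed. Fewer Müller glia or vascular cells are argued against too: their marker means less 2 SE were no lower than −0.073, and the list mean plus 2 SE was −0.17. These SE are over the genes of each list, which are not independent, and do not measure the spread between pools of mice. In 1 of the 10 splits of the 6 libraries, the real one, the list mean was this far from 0 (highest other 0.16). The list passed the camera test at the preset correlation in 4 of the 9 other splits too (lowest adjusted p 2.89e-05). Each of these 9 splits is uneven in genotype, so a real difference would enter it in part, and its pass cannot count against one. Also, 10 splits are too few for a share under 0.05. Time in the light, handling and time of dissection within the collection window stay open as untested causes, beside a response to the loss of Dicer1 in rods.

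The libraries differed along an axis that runs through both groups: setting cKO replicates 2 and 3 and control replicate 2 against the rest gave 3468 genes at an unadjusted limma p under 0.05, against 719 for the real groups. This split is the largest of the 9 others, and with 2 of 3 cKO libraries on 1 side it overlaps in part with genotype. The first residual component held 57.3% of the variance left after the group means, and its loadings followed gene length with a Spearman coefficient of 0.508 across genes, which are not independent replicates. After a correction for gene length the split gave 2831 such genes, and with the lens level as a covariate 3289, so each is argued against as the whole cause. These are counts, and whether the genes are the same was not checked. Fragment length or RNA integrity could enter in other ways, and no biological explanation was tested. The genotype fold change had a Spearman coefficient of −0.0039 with gene length across genes, but the relation did not run 1 way: its median was −0.033 in 1045 genes up to 1 kb, −0.0088 from 1 to 2 kb, 0.0098 from 2 to 4 kb, −0.0027 from 4 to 8 kb and −0.080 in 543 genes over 8 kb.

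The 1 gene called higher was matched or exceeded in 2 of the 10 splits, the real one included (highest other 2). For gene lists, the 1 called higher was matched or exceeded in 9 splits (highest other 6) and the 2 called lower in 8 (highest other 9). Which side of a mixed split counts as higher is arbitrary, so these matches by direction mean little. In either direction, 3 lists were called for the real groups and between 2 and 9 in the other splits. The other splits are uneven in genotype, so a real difference would enter them in part. With 10 splits no share can fall under 0.05. A count of 0 is matched in 10 of 10 splits whatever the values, so this comparison says nothing about the 0 genes called lower (highest other 2) or the 0 microRNA families called in either direction (highest other 0).

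As a test of the hypothesis that DNA flanking the transgene or the floxed allele differs between the groups, genes with low p were checked for neighbours on a chromosome. Among the 50 genes with the smallest p that have a position, 2 pairs lay within 10 tested genes of each other, against a median of 2 and a 95th percentile of 5 in 10000 random sets (permutation p = 0.622). A bound at the median had been set in advance as evidence against it, but 2 pairs lie inside the spread of random sets, so a few linked genes are neither shown nor excluded.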
